A study of Homo sapiens with 9 samples.

How the data were processed

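The material is RNA sequencing of MDA-MB-231 cells in hanging drop culture, in 9 libraries of 3 groups with 3 replicates each (siC, siERRa-D and siERRa-I). Per the labels' protocols, siRNA was transfected with a commercial reagent, and RNA and mRNA libraries were made with commercial kits. Per the submitters' processing notes, reads were inspected with FastQC, aligned to hg38 with STAR 2.7.3a and counted per gene with HTSeq. The version listed there for HTSeq could not be matched to a release and is left out, and the annotation and the strand setting are not given in the sources used here. The deposited values are raw counts per gene symbol, whole numbers that were not normalized. A deposited table of the whole series held the same 9 columns as the files of single samples, equal in all 28278 genes, and no column of another series.

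Entries that name no gene were left out of library sizes and tests. Uniquely aligned reads outside annotated genes made up 20.5% to 25.1% of the reads that were either outside genes, ambiguous or assigned to genes, and ambiguous reads 1.16% to 1.31%. The 10 genes with most reads held 4.41% to 5.64% of the reads in genes. Depth ranged from 32295434 to 38018517 reads in genes. Libraries of one group differed by far more than counting noise, with a chi-square per gene of 10.8 to 56.2 between pairs, so no library was counted as a copy of another. Reads of genes with near-identical copies can be lost or split in such counting, and no correction was applied.

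Counts were analysed in R 4.3.3 with edgeR 4.0.16. Genes were kept by filterByExpr with the groups, which left 14435, and scaled by TMM. Dispersions were estimated robustly (common biological coefficient of variation 0.144), and contrasts were tested with the quasi-likelihood F test in 1 fit of all 9 libraries, with Benjamini-Hochberg adjustment over the tested genes and a threshold of 0.05. The contrasts were each siRNA against siC, their average against siC, and siERRa-I against siERRa-D. Standard errors are the absolute log2 fold change divided by the square root of F. A gene changed the same way by both siRNAs passed 0.05 in both single comparisons with the same sign. For the shared controls, 20 sets of 9 unchanged libraries were simulated. CPM values use TMM-scaled library sizes.

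The design, the lists of genes and the rule for named genes were fixed before the data were examined. There were 27 lists with 822 entries, on ERRα and its coactivators, textbook ERRα targets, mitochondrial metabolism, ribosomes, glycolysis, hypoxia, cholesterol, the cell cycle, actin, integrins, matrix, the epithelial to mesenchymal transition, interferon, NF-kappaB and cytokines, stress responses, autophagy and lysosomes, TGF-beta targets, histones and markers of luminal, leukocyte, fibroblast and endothelial cells. Of the entries 809 were in the table and 723 were tested. The 24 lists with at least 5 tested members were tested with camera (limma 3.58.1, preset correlation 0.01, two-sided), with adjustment over 72 tests of 3 comparisons. None of the 22 list calls held with a correlation estimated for each list, which gave the highest adjusted p of all alternatives for each of the 22. The rule named ERRα and its coactivators, the 12 largest changes each way shared by both siRNAs (ranked by the smaller change), the 6 largest each way for each siRNA and for their difference among genes whose groups did not overlap, and up to 4 members of each list that passed or held at least 3 genes changed by both, with an average log2 CPM of at least 1 except for list members. The text does not print every gene that the rule picks. Groups of 3 fail to overlap by chance in 10% of genes. List members named to give an exception or another example (CALR, COL12A1, LAMA5, CD3D and PDGFRB) were picked after their values were seen.

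The labels give the groups the same replicate numbers. Deviations from the group means correlated at 0.43 to 0.69 between libraries of the same number and at -0.52 to -0.07 between different numbers, and all 9 libraries matched their own number best in both other groups. The numbers therefore pair the libraries by the data, although the labels do not say what a number stands for. The planned fit has no block, and the fit with the number as a block is given beside many of the counts and calls that it changed, not all.

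Alternatives were DESeq2 1.42.0, RLE size factors, no low-count filter, a minimum mean of 2 CPM, only the groups compared in the fit, the replicate block, leaving out each library, and, for lists, an estimated correlation and fry. Corrections for GC content and transcript length were added after the data were seen. Gene positions, GC content, lengths and 3' untranslated regions came from GENCODE 29 on GRCh38, the same build as hg38, matched by symbol, and 13698 tested symbols had a position. Motifs of 7 bases in 3' untranslated regions were scanned in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and figures were drawn with matplotlib 3.10.9.

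The steps were tested on simulated data. In a simulated comparison of siERRa-D with siC over 14435 genes, edgeR recovered 90 of 100 genes changed by 1 on the log2 scale and 23 of 100 changed by 0.5, and called 8 of 14235 unchanged genes, where DESeq2 called 163. With camera (limma), a simulated list of 25 genes raised by 0.5 was called, while an unchanged list was not. A planted GC trend gave 2912 calls in 13727 genes before the correction and 0 after it. The motif scan recovered a planted effect of -0.3 in 10 of 10 runs over 12407 genes.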

Results

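RNA was sequenced from MDA-MB-231 cells, an established human breast cancer line of mesenchymal appearance that lacks the estrogen receptor, grown in 3 dimensions as hanging drops. The cells had been transfected with a control siRNA (siC) or with 1 of 2 siRNAs against ERRα, called siERRa-D and siERRa-I. ERRα, encoded by ESRRA, is an orphan nuclear receptor that acts with the PGC-1 coactivators on genes of energy metabolism. Each group held 3 libraries. Reads assigned to genes numbered 35426157, 35163956 and 38018517 in the siC libraries, 37691143, 32295434 and 35715984 in siERRa-D, and 32704870, 32696312 and 32913789 in siERRa-I. Of the 28278 genes listed, 14435 passed the low-count filter and were tested. The first principal component held 37.8% of the variance and ordered the groups as siC, siERRa-I and siERRa-D. The second held 21% and separated the replicate numbers, so values with the replicate number as a block are given beside many of the counts and calls that it changed, not all. Nothing in the labels says that the 3 libraries of a group came from separate cultures, so the p-values measure only the spread between these libraries. Below, levels are means ± SD in CPM, read counts scaled to library size, with n = 3 libraries per group, and errors of log2 fold changes are standard errors.

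The target gene was lower in all 6 libraries transfected with an ERRα siRNA. ESRRA (chromosome 11, 64305572 to 64316743, hg38) had 356, 312 and 311 reads in the siC libraries, 114, 49 and 57 in siERRa-D and 89, 70 and 70 in siERRa-I. Its level was 9.11 ± 0.755 CPM in siC, 2.09 ± 0.787 CPM in siERRa-D and 2.24 ± 0.279 CPM in siERRa-I. The log2 fold change was -2.11 ± 0.23 with siERRa-D (edgeR adjusted p = 0.000106) and -2.02 ± 0.23 with siERRa-I (edgeR adjusted p = 0.00054). These leave 23.1% and 24.6% of the control level. The difference between the siRNAs was 0.09 on the log2 scale, with a 95% interval from -0.43 to 0.61. ESRRA has a processed pseudogene, so some of its reads could be assigned elsewhere. PPARGC1A, which encodes the coactivator PGC-1α, rose 3.04-fold with siERRa-D (edgeR adjusted p = 0.000201) and 1.90-fold with siERRa-I (edgeR adjusted p = 0.0111). Without siERRa-I replicate 3 the latter had an adjusted p of 0.0513 in edgeR. PPARGC1B, which encodes PGC-1β, fell to 0.605 times the control with siERRa-D (edgeR adjusted p = 0.00441), and with siERRa-I it stood at 0.812 times (edgeR adjusted p = 0.207, and 0.04 with the replicate block). NRIP1, a corepressor, was at 0.720 times the control with siERRa-D (edgeR adjusted p = 0.0164) and at 0.863 times with siERRa-I (edgeR adjusted p = 0.298, and 0.023 with the replicate block). The NRIP1 call was lost without siC replicate 2 (adjusted p = 0.0633) or siERRa-D replicate 3 (adjusted p = 0.06). PPRC1 and KDM1A did not pass with either siRNA. The relatives ESRRB and ESRRG had at most 3 reads in any library and were not tested.

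**Figure D1:**
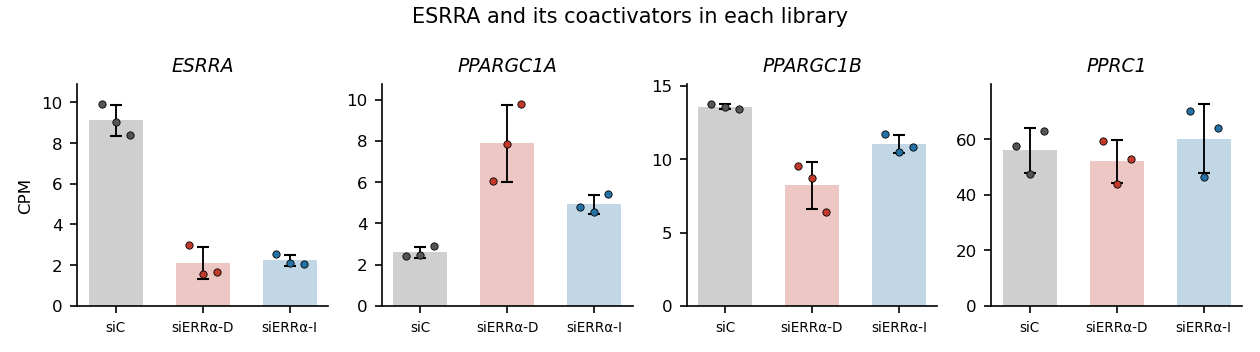
Level of ESRRA and of 3 coactivator genes in CPM (vertical axes, each from 0) in the 3 groups; points are libraries, bars are means and error bars are SD (n = 3). ESRRA stood at 9.11 CPM in siC and at 2.09 and 2.24 CPM with the siRNAs, while PPARGC1A was higher with both.

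Comparing each siRNA with siC and keeping genes called in the same direction by both asks which changes do not depend on one reagent. CCN2, a matricellular protein, went from 2523 ± 721 CPM in siC to 383 ± 92.7 CPM with siERRa-D and 427 ± 31.2 CPM with siERRa-I (edgeR adjusted p = 1.84e-05 and 7.17e-05). SPARC, a collagen-binding matricellular protein, was at 0.235 and 0.145 times the control, and ANGPT2, the vascular growth factor angiopoietin-2, at 0.107 and 0.234 times. Other genes with large falls were SUN3, of the nuclear envelope (0.0519 and 0.115 times), MAMDC2 (0.0953 and 0.145 times), the growth factor FGF1 (0.240 and 0.222 times) and CYP24A1, the vitamin D 24-hydroxylase (0.105 and 0.235 times). CTSW, CST1 (adjusted p = 0.0656 with siERRa-I without a low-count filter in edgeR), HPCAL4 and RELN also fell, at 0.0959 to 0.243 times the control. RELN lost its call with siERRa-I without siC replicate 1, siERRa-I replicate 2 or siERRa-I replicate 3 (adjusted p = 0.0735, 0.0586 and 0.0561 in edgeR). Its log2 fold change was then -1.32, -1.86 and -2.13. In siC replicate 1 it stood at 9.77 CPM, against 2.6 and 3.98 CPM in siC replicates 2 and 3.

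Among the rises, SPNS2, a sphingosine-1-phosphate transporter, rose 5.58-fold with siERRa-D and 4.53-fold with siERRa-I (edgeR adjusted p = 0.000262 and 0.00161). CALB2, the calcium-binding protein calretinin, went from 21.9 ± 2.62 CPM to 68.7 ± 3.52 and 64.4 ± 4.11 CPM. FOXQ1, a forkhead transcription factor, rose 6.87-fold with siERRa-D and 2.37-fold with siERRa-I, and this difference passed its own test (edgeR adjusted p = 0.000262). PLEC, which encodes the cytoskeletal linker plectin, rose 2.48-fold and 2.15-fold. GATD1, MIDN, ZBTB45, GET4 and LHPP rose 2.15-fold to 2.72-fold. RAMP1 rose 3.29-fold and 2.49-fold, and the latter call was lost without siC replicate 1, siC replicate 3, siERRa-I replicate 1 or siERRa-I replicate 2 (adjusted p = 0.101, 0.0889, 0.088 and 0.0501 in edgeR). PRKXP1, a processed pseudogene, also rose, but its reads may be shared with its parent gene.

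**Figure D2:**
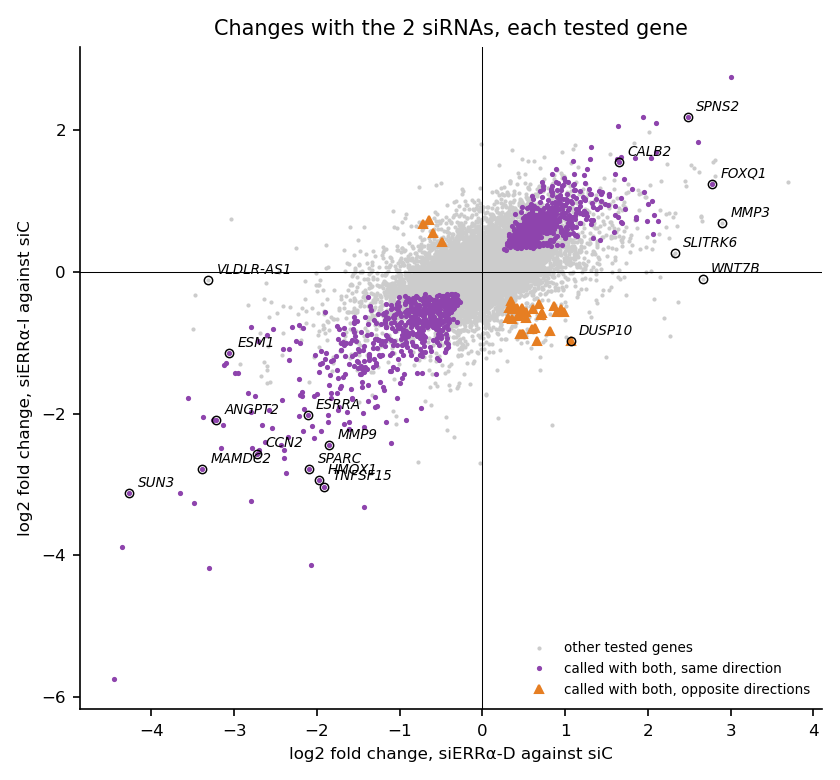
Log2 fold change with siERRa-I (vertical axis) against that with siERRa-D (horizontal axis), both relative to siC, for the 14435 tested genes; purple points were called in the same direction by both (1146 genes), orange triangles in opposite directions (35 genes), and grey points are the rest. CCN2, SPARC and ANGPT2 lie at the lower left with ESRRA, and SPNS2, CALB2 and FOXQ1 at the upper right.

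In all, 1146 genes changed the same way with both siRNAs, 540 up and 606 down. With the replicate block there were 3639, 1813 up and 1826 down. At least a 2-fold change with both was met by 53 rises and 156 falls. Of the 1146 genes, 160 also differed between the siRNAs, and 135 of these moved further with siERRa-D. The average of both siRNAs against siC called 3448 genes, 1614 up and 1834 down (7189 with the block, 3585 up and 3604 down). Independent lists of these sizes would share 122 rises and 148 falls and hold 269 genes of opposite direction, against 35 observed. Simulated unchanged groups, with simulated controls shared by both comparisons, had between 0 and 2 shared genes in each direction. With no true change few genes pass at all. This count therefore cannot show how many of the 1146 genes come from the shared controls. The simulation also left out the pairing by replicate number. Across genes, which are not independent replicates, the log2 fold changes correlated at 0.64, against 0.50 (0.46 to 0.55) in the simulation. Their covariance was 0.17 against a simulated 0.0313, a difference of 0.139. The same sign was shared by 71.3% of genes, against a simulated 66.7%. The 3 control libraries were too few to give each siRNA controls of its own, and part of the excess may come from the shared controls. The count of 1146 fell to 593 without siC replicate 1, 569 without siC replicate 2 and 536 without siERRa-I replicate 3. The averaged count fell to 2269 without siC replicate 1 and 1945 without siC replicate 2.

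Several lists of genes held members lower with both siRNAs. Of all 14435 tested genes, 606 fell with both. With siERRa-D, TGF-beta targets had 5 rises and 6 falls, and integrins had 6 and 3. NF-kappaB genes had 3 and 6, and matrix genes 10 and 13. None of these lists passed in camera with siERRa-D. With the preset correlation, all were lower with siERRa-I than with siERRa-D. Their members lower with both therefore do not stand for a fall of the whole list. Of 41 tested genes of the extracellular matrix and its remodelling, 9 fell with both and 1 rose with both (15 and 3 with the replicate block). Besides CCN2 and SPARC, the gelatinase gene MMP9 was at 0.277 and 0.183 times the control (edgeR adjusted p = 0.000188 and 0.000151). Of 18 tested TGF-beta target genes, 6 fell with both (6 fell and 1 rose with the block), among them the transcription factor BHLHE40 (0.443 and 0.509 times) and the matrix protein gene TGFBI (0.694 and 0.424 times). Of 24 NF-kappaB and cytokine genes, 5 fell with both (7 fell and 1 rose with the block), among them the interleukin genes IL1B (0.301 and 0.267 times, from 306 ± 93.6 CPM) and IL11 (0.526 and 0.234 times). Of 30 unfolded protein and integrated stress response genes, 5 fell with both (16 with the block), among them the receptor gene VLDLR (0.317 and 0.437 times) and the transcription factor ATF3 (0.387 and 0.442 times). Only this list passed in the same direction with both siRNAs (camera adjusted p = 1.56e-05 and 7.41e-06, and 0.342 and 0.333 with an estimated correlation). Between the siRNAs the list did not pass (camera adjusted p = 0.382). Of 23 glycolysis genes, 5 fell with both (7 fell and 2 rose with the block), among them the glucose transporter gene SLC2A3 (0.601 and 0.371 times) and PGK1 (0.713 and 0.565 times). Of 13 integrins, 3 fell with both (5 fell and 2 rose with the block). These were ITGA1, ITGB3 and ITGA11, and all 3 lost the call with siERRa-I without siC replicate 1 (adjusted p = 0.0848, 0.0559 and 0.0578 in edgeR) or siERRa-I replicate 3 (adjusted p = 0.0948, 0.0577 and 0.0718 in edgeR). With the block and all libraries, their edgeR adjusted p with siERRa-I was 0.00187, 1.11e-06 and 0.000317. Of 22 hypoxia response genes, 3 fell with both (AK4, ERO1A and EGLN3; 9 with the block), and each lost a call when 1 library was left out, with adjusted p up to 0.116. The calls of PGK1, IL1B, VLDLR, ATF3 and BHLHE40 with siERRa-I were kept without any single library. PGK1 with siERRa-D had an adjusted p of 0.0508 without siERRa-D replicate 2. VLDLR overlaps an antisense gene, and the strand setting of the counting was not given in the sources used here, so its count is uncertain.

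Of 46 actin regulation and focal adhesion genes, 3 fell and 1 rose with both siRNAs (8 and 6 with the replicate block), and the list did not pass in any comparison. MYLK, myosin light chain kinase, fell to 0.559 and 0.623 times the control (edgeR adjusted p = 0.000106 and 0.00106). Of 19 genes of the epithelial to mesenchymal transition, 2 fell and 1 rose with both (2 and 2 with the block). SNAI1, which encodes a repressor of E-cadherin, fell to 0.527 and 0.498 times, as did the desmosome gene DSP (0.595 and 0.548 times). Its relative SNAI2 rose 3.04-fold with siERRa-D and stood at 1.74-fold with siERRa-I (edgeR adjusted p = 0.024, and up to 0.0967 without siC replicate 1, siC replicate 2, siERRa-I replicate 2 or siERRa-I replicate 3). Among 8 endothelial markers, 3 were tested and all 3 fell with both siRNAs, alongside the matrix genes. KDR went from 4.51 ± 1.51 CPM to 1.23 ± 0.24 and 1.11 ± 0.123 CPM. CDH5 went from 3.67 ± 2.99 CPM to 0.176 ± 0.103 and 0.244 ± 0.116 CPM, and PECAM1 from 9.50 ± 1.44 CPM to 4.48 ± 0.658 and 3.76 ± 0.765 CPM.

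**Figure D3:**
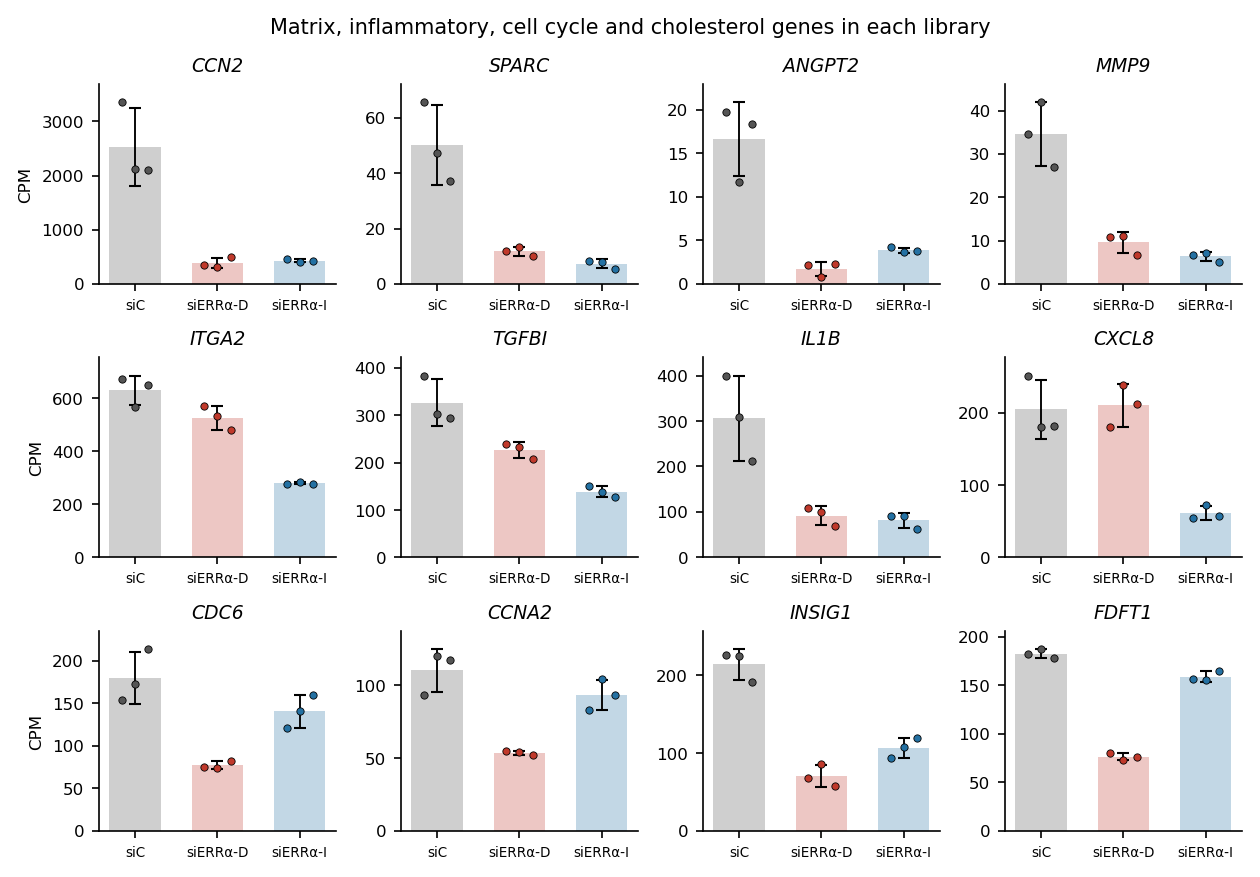
Level of 12 named genes in CPM (vertical axes, each from 0) in the 3 groups; points are libraries, bars are means and error bars are SD (n = 3). CCN2, SPARC, ANGPT2, MMP9 and IL1B were lower with both siRNAs, CXCL8 and ITGA2 passed with siERRa-I and not with siERRa-D, and CDC6, CCNA2 and FDFT1 with siERRa-D and not with siERRa-I, but with the replicate block all of these except CXCL8 passed with both (edgeR adjusted p = 0.00517 for ITGA2 with siERRa-D, and 0.000566, 0.0208 and 0.0194 for CDC6, CCNA2 and FDFT1 with siERRa-I).

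The comparison of siERRa-D with siC called 4099 genes, 1969 up and 2130 down (7630 with the replicate block, 3918 up and 3712 down). Genes of cholesterol biosynthesis fell together. Of 25 tested members 18 fell and none rose, with a median log2 fold change of -0.88 (camera adjusted p = 7.33e-14, and adjusted p = 0.0953 with an estimated correlation). Adjusted over the list alone 19 fell and 1 rose, and with the block 21 fell and 1 rose. INSIG1, a sterol-regulated inhibitor of SREBP processing, went from 214 ± 19.6 to 70.8 ± 14.6 CPM (edgeR adjusted p = 5.2e-05), and FDFT1, squalene synthase, from 183 ± 4.74 to 76.5 ± 3.42 CPM (edgeR adjusted p = 1.15e-05). The sterol transfer protein gene STARD4 and the demethylation enzyme gene MSMO1 were at 0.371 and 0.350 times the control.

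Genes of the cell cycle and DNA replication fell with siERRa-D as well. Of 42 members 28 fell and none rose, with a median log2 fold change of -0.56 (camera adjusted p = 5.1e-11, and adjusted p = 0.392 with an estimated correlation), and 31 fell when adjusted over the list alone. CDC6, a replication licensing factor, went from 180 ± 30.4 to 77.1 ± 4.72 CPM, and CCNA2, cyclin A2, from 110 ± 14.6 to 53.7 ± 1.34 CPM (edgeR adjusted p = 0.00014 and 0.000183). The mitotic kinase genes AURKB and BUB1 were at 0.515 and 0.627 times the control. Of 30 unfolded protein and integrated stress response genes 13 fell and 1 rose, with a median of -0.40 (camera adjusted p = 1.56e-05, and adjusted p = 0.342 with an estimated correlation). Adjusted over the list alone 15 fell and 1 rose, and with the replicate block 20 fell and 3 rose. PSAT1, of serine synthesis, was at 0.335 times the control and EDEM1, of endoplasmic reticulum degradation, at 0.634 times. The member that rose, CALR, which encodes the chaperone calreticulin, was chosen after its value was seen (log2 fold change 0.40, edgeR adjusted p = 0.00964).

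The autophagy and lysosome list rose with siERRa-D. Of 29 members 9 rose and 2 fell, both over all genes and adjusted over the list alone, with a median log2 fold change of 0.22 (camera adjusted p = 0.0217, and adjusted p = 0.471 with an estimated correlation). With the replicate block 16 rose and 3 fell. CTSD, the lysosomal protease cathepsin D, rose from 223 ± 23.7 to 540 ± 73.1 CPM (edgeR adjusted p = 0.000251). The members that fell were NPC1, a lysosomal cholesterol transporter, and GLA, a lysosomal hydrolase, at 0.606 and 0.733 times the control, and neither call held without siC replicate 1, siERRa-D replicate 2 or siERRa-D replicate 3 (adjusted p between 0.0577 and 0.0793 in edgeR). Those fits had no replicate block. With the block and all libraries, the edgeR adjusted p was 1.26e-06 for NPC1 and 0.000679 for GLA. The list lost its call without siC replicate 2 (camera adjusted p = 0.0532) or siC replicate 3 (camera adjusted p = 0.08), with 0.00301 to 0.471 as the range over all alternatives.

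Besides FOXQ1 and SPNS2, single genes with large rises with siERRa-D were MMP3, the matrix protease stromelysin-1 (7.46-fold), the signalling ligand gene WNT7B (6.33-fold), the protease inhibitor genes SLPI (6.28-fold) and PI3 (5.17-fold), C3, complement component 3 (6.24-fold), and SLITRK6 (5.01-fold). Their adjusted p in edgeR lay between 4.06e-05 and 0.00333. Large falls among genes not named above were those of CLIC5 (0.114 times), ESM1, which encodes the proteoglycan endocan (41.2 ± 14.1 to 4.93 ± 1.14 CPM), and the GABA receptor gene GABBR2 (0.149 times). KRTAP4-8 (0.144 times), VLDLR-AS1 (0.101 times) and HHIP-AS1 (0.153 times) also fell. They belong to a family of near-identical genes or lie antisense to other genes, so their counts are uncertain. The count of 4099 stayed within 1.5 times of itself when any single library was left out, and the median log2 fold change of all genes was 0.022.

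With siERRa-I, 1898 genes were called against siC, 892 up and 1006 down (5852 with the replicate block, 2876 up and 2976 down). Inflammatory and matrix genes fell together. Of 24 NF-kappaB and inflammatory cytokine genes 10 fell and none rose, with a median log2 fold change of -0.78 (camera adjusted p = 8.21e-11, and adjusted p = 0.342 with an estimated correlation). Adjusted over the list alone 13 fell, and with the replicate block 18 fell and 1 rose. CXCL8, the chemokine interleukin-8, went from 205 ± 40.5 to 61.2 ± 9.40 CPM (edgeR adjusted p = 0.000165), and IL1A from 351 ± 44.9 to 110.0 ± 24.3 CPM (edgeR adjusted p = 0.000775). Of 41 matrix genes 16 fell and 2 rose, with a median of -0.40 (camera adjusted p = 1.31e-12, and adjusted p = 0.132 with an estimated correlation), and 18 fell and 3 rose when adjusted over the list alone (23 fell and 4 rose with the block). The 2 that rose were COL12A1, a collagen gene, and LAMA5, a laminin gene (log2 fold changes 1.02 and 0.68, edgeR adjusted p = 0.0117 and 0.048), both chosen after their values were seen. Of 18 TGF-beta target genes 8 fell and none rose, with a median of -0.52 (camera adjusted p = 2.2e-11, and adjusted p = 0.094 with an estimated correlation; also 8 adjusted over the list alone; 10 fell and 1 rose with the block). Of 13 integrins 6 fell and none rose, with a median of -0.42 (camera adjusted p = 0.000182, and adjusted p = 0.132 with an estimated correlation; also 6 adjusted over the list alone). ITGA2, a collagen receptor subunit, went from 630 ± 55.7 to 280 ± 4.63 CPM (edgeR adjusted p = 0.00011). With the block 2 integrins rose and 9 fell.

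Stress, hypoxia and lysosome genes were also lower with siERRa-I. Of 30 unfolded protein and integrated stress response genes 7 fell and none rose (8 adjusted over the list alone, 21 with the replicate block), with a median of -0.26 (camera adjusted p = 7.41e-06, and adjusted p = 0.333 with an estimated correlation). Of 22 hypoxia response genes 6 fell and none rose, as when adjusted over the list alone, and 13 fell with the block (median -0.30, camera adjusted p = 0.000478, and adjusted p = 0.168 with an estimated correlation). P4HA2, a collagen prolyl hydroxylase, was at 0.562 times the control (edgeR adjusted p = 0.0028). Of 29 autophagy and lysosome genes 6 fell and 1 rose (7 and 1 adjusted over the list alone, 15 and 3 with the block), with a median of -0.25 (camera adjusted p = 0.00559, and adjusted p = 0.392 with an estimated correlation). The member that rose was ATP6V0D1, a proton pump subunit (1.32-fold, edgeR adjusted p = 0.0393, and up to 0.148 without siC replicate 1, siC replicate 2, siERRa-D replicate 2, siERRa-D replicate 3, siERRa-I replicate 1 or siERRa-I replicate 3). Of 23 glycolysis genes 5 fell and none rose (5 fell and 1 rose adjusted over the list alone, 10 fell and 3 rose with the block), with a median of -0.15 (camera adjusted p = 0.0217, and adjusted p = 0.748 with an estimated correlation). HK1, a hexokinase, was at 0.701 times the control, while HK2 was at 0.686 times (edgeR adjusted p = 0.0423, and up to 0.122 when any 1 of 7 libraries was left out). The glycolysis call was lost without siERRa-I replicate 2 (camera adjusted p = 0.135) or siC replicate 3 (camera adjusted p = 0.0563) and in fry (adjusted p = 0.164), in a range of 0.00144 to 0.748 over all alternatives.

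Besides genes named above, such as SUN3 and SPARC, single genes with large falls with siERRa-I were TNFSF15, a TNF family ligand (0.122 times), HMOX1, heme oxygenase 1 (136 ± 44.0 to 17.7 ± 4.50 CPM), MMP9 (0.183 times), SIGLEC15 (0.187 times), the RNA gene LINC00942 (0.229 times), and CSF1, macrophage colony-stimulating factor (299 ± 109 to 68.9 ± 10.6 CPM). Their edgeR adjusted p lay between 5.97e-05 and 0.00511. All 6 were also lower with siERRa-D, but without siC replicate 1 the calls of TNFSF15 (adjusted p = 0.0678) and SIGLEC15 (adjusted p = 0.0673) with that siRNA were lost, and that of SIGLEC15 also without siERRa-D replicate 3 (adjusted p = 0.0525). Besides genes named above, such as SPNS2 and CALB2, large rises were those of TMEM80 (2.96-fold), SEC31B, of vesicle coats (2.73-fold), ITGBL1 (2.50-fold), TRIM66 (2.42-fold), SAMD10 (2.41-fold) and TFB1M, a mitochondrial ribosomal RNA methyltransferase (2.33-fold). These 6 were also called higher with siERRa-D, SEC31B not without siERRa-D replicate 2 (adjusted p = 0.05) or siC replicate 3 (adjusted p = 0.0501). The share of uniquely aligned reads outside annotated genes was 21.8% ± 1.1 (SD, n = 3) in siC, 23.0% ± 1.7 in siERRa-D and 24.2% ± 0.8 in siERRa-I. A two-sided exact permutation test gave p = 0.1 for siERRa-I against siC, the smallest it can give, and exact p = 0.4 for siERRa-D. That test ignores the replicate numbers, and paired by number the share was above that of siC in 3 of 3 pairs with either siRNA. The count of 1898 fell to 962 without siC replicate 1, 946 without siC replicate 2 and 797 without siERRa-I replicate 3.

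The direct comparison of siERRa-I with siERRa-D asks where reagents against the same target differ. It called 2375 genes, 1217 higher and 1158 lower with siERRa-I (5872 with the replicate block, 2885 and 2987). Cell cycle genes were higher with siERRa-I than with siERRa-D in 35 of 42 members and lower in 1, with a median log2 difference of 0.64 (camera adjusted p = 4.46e-22, and adjusted p = 0.178 with an estimated correlation; 41 and 1 adjusted over the list alone). Against siC, 4 of these genes rose with siERRa-I and none fell, which did not pass as a list (camera adjusted p = 0.25, but 0.0129 without siC replicate 3; 4 rose adjusted over the list alone; 13 rose and 5 fell with the replicate block). Cholesterol biosynthesis genes were higher in 17 of 25 members and lower in none, with a median of 0.64 (camera adjusted p = 3.68e-16, and adjusted p = 0.094 with an estimated correlation; 19 adjusted over the list alone). FDFT1, STARD4 and MSMO1 differed by 2.08-fold, 2.14-fold and 2.45-fold (edgeR adjusted p = 0.000143, 0.00055 and 0.000907). Against siC with siERRa-I, 1 of the 25 genes fell, INSIG1 (0.498 times, edgeR adjusted p = 0.00189), and the list did not pass (camera adjusted p = 0.356; 1 fell adjusted over the list alone), while with the replicate block 11 fell and 4 rose. Histone genes whose RNA lacks poly(A) tails were higher as a list (26 tested of 52 listed, 2 higher and 1 lower, median 0.67, camera adjusted p = 0.0113, and adjusted p = 0.748 with an estimated correlation). How evenly the mRNA libraries captured such RNA was not tested, and H3C2, named below, had an average log2 CPM of only 0.51. With the block 11 were higher and 1 lower, and adjusted over the list alone 2 were higher and 1 lower. The histone call was lost without siERRa-I replicate 1 (camera adjusted p = 0.166), without siERRa-D replicate 2 (camera adjusted p = 0.0733), with a minimum mean of 2 CPM (camera adjusted p = 0.242) and in fry (adjusted p = 0.105), in a range of 0.000423 to 0.748. H3C2 was 1.83-fold higher, but not past the threshold without siERRa-I replicate 1, siERRa-D replicate 2, siERRa-I replicate 2 or siERRa-D replicate 3 (edgeR adjusted p = 0.0594, 0.067, 0.0606 and 0.0544). H2AC6 was at 0.657 times, and not past it without siERRa-I replicate 2, siERRa-D replicate 3 or siERRa-I replicate 3 (edgeR adjusted p = 0.0786, 0.0702 and 0.0699).

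Of 6 lists lower with siERRa-I than with siERRa-D, the autophagy and lysosome genes went lower in 14 of 29 members and higher in none (median -0.40, camera adjusted p = 1.36e-09, and adjusted p = 0.0953 with an estimated correlation; 19 and 1 adjusted over the list alone and with the block). CTSD was at 0.457 times its siERRa-D level (edgeR adjusted p = 0.00107). NF-kappaB and cytokine genes were lower in 10 of 24 and higher in none (median -0.65, camera adjusted p = 7.31e-08, and adjusted p = 0.415 with an estimated correlation; 13 and 1 adjusted over the list alone; 17 and 1 with the block), CXCL8 at 0.291 times. Integrins were lower in 8 of 13 and higher in none (median -0.68, camera adjusted p = 1.34e-07, and adjusted p = 0.094 with an estimated correlation; 10 and 1 adjusted over the list alone and with the block). TGF-beta target genes were lower in 7 of 18 and higher in none (median -0.57, camera adjusted p = 4.49e-06, and adjusted p = 0.132 with an estimated correlation; 9 adjusted over the list alone; 12 lower and 1 higher with the block). Matrix genes were lower in 15 of 41 and higher in 4 (median -0.46, camera adjusted p = 1.29e-05, and adjusted p = 0.342 with an estimated correlation; 20 and 6 adjusted over the list alone; 22 and 9 with the block). FN1, fibronectin, stood at 438 ± 70.4 CPM in siC, 1013 ± 144 CPM with siERRa-D and 477 ± 62.5 CPM with siERRa-I (edgeR adjusted p of the difference = 0.000907). Genes of the epithelial to mesenchymal transition were lower in 4 of 19 and higher in 1 (median -0.23, camera adjusted p = 0.00981, and adjusted p = 0.168 with an estimated correlation; 7 and 1 adjusted over the list alone; 10 and 2 with the block). That list holds the desmosome gene DSP beside SNAI1 and FN1, so its direction does not tell more transition from less.

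Single genes with large differences were CLDN1, a tight junction claudin (0.140 times its siERRa-D level with siERRa-I), PI3 (0.144 times), WNT7B (0.147 times), MMP3 (0.215 times), SLITRK6 (0.240 times) and DUSP10, a phosphatase of stress-activated kinases (0.242 times). Higher with siERRa-I were ESM1 (3.77-fold) and RBFOX3, a splicing factor (3.92-fold, edgeR adjusted p = 0.00134), which stood at 0.587 times the control with siERRa-D (edgeR adjusted p = 0.0758, and 0.00254 with the block). VLDLR-AS1, GACAT2, KRTAP4-8 and SHANK2 were also higher, the first 3 with the uncertainty of antisense or near-identical genes. SHANK2 lost its call without any 1 of 5 siRNA libraries, all but siERRa-I replicate 3, with adjusted p between 0.0555 and 0.12. DUSP10 went in opposite directions against siC, at 2.09 times with siERRa-D and 0.507 times with siERRa-I. The count of 2375 fell to 1254 without siERRa-D replicate 2, 1557 without siERRa-D replicate 3, 1394 without siERRa-I replicate 2 and 1192 without siERRa-I replicate 3.

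Mitochondrial metabolism is the textbook field of ERRα. Of 39 tested textbook ERRα target genes, 1 rose and 3 fell with siERRa-D (camera adjusted p = 0.414; 2 fell adjusted over the list alone; 5 rose and 16 fell with the replicate block). With siERRa-I 3 fell and none rose, with a median of -0.15 (camera adjusted p = 0.0301, and adjusted p = 0.369 with an estimated correlation; 3 adjusted over the list alone; 15 fell and 2 rose with the block). That call was lost without siERRa-I replicate 1 (camera adjusted p = 0.093), without siC replicate 2 (camera adjusted p = 0.0744) and with a minimum mean of 2 CPM (camera adjusted p = 0.0859), in a range of 0.0108 to 0.369. MMP1, interstitial collagenase, was at 0.340 and 0.604 times the control with siERRa-D and siERRa-I (edgeR adjusted p = 4.06e-05 and 0.00647). CPT1A, which admits fatty acids to mitochondria, was at 0.990 times with siERRa-D and 0.471 times with siERRa-I (edgeR adjusted p = 0.946 and 0.000991), and this difference passed (edgeR adjusted p = 0.000675). SDHB, a subunit of succinate dehydrogenase, was at 0.750 times with siERRa-D (edgeR adjusted p = 0.00906) and 0.828 times with siERRa-I (edgeR adjusted p = 0.0909, and 0.00298 with the block). NDUFS1, of complex I, was at 1.23 and 1.24 times and passed with both siRNAs only with the block (edgeR adjusted p = 0.061 and 0.0838, and 0.000771 and 0.000952 with the block).

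With all libraries and the preset correlation, no list of respiratory chain, citrate cycle, fatty acid oxidation or ribosomal genes passed in any of the 3 comparisons. Complexes II to V passed with siERRa-I without siC replicate 1 (camera adjusted p = 0.0115). Cytosolic ribosomal proteins passed between the siRNAs without siERRa-I replicate 1, siERRa-I replicate 2 or siERRa-D replicate 3 (camera adjusted p = 0.0486, 0.023 and 0.0123). In fry, mitochondrial ribosomal proteins (adjusted p = 0.0419) and the citrate cycle (adjusted p = 0.0295) passed with siERRa-D, and fatty acid oxidation between the siRNAs (adjusted p = 0.0347). Of 35 complex I subunits 5 rose and 1 fell with siERRa-D and none was called with siERRa-I, with medians of 0.08 and 0.05 (camera adjusted p = 0.363 and 0.661). Of 41 genes of complexes II to V and cytochrome c, 4 and 2 fell, with medians of -0.05 and -0.09 (camera adjusted p = 0.378 and 0.105). Of 22 citrate cycle genes 1 rose and 6 fell with siERRa-D and none was called with siERRa-I (camera adjusted p = 0.44 and 0.518). Of 22 fatty acid oxidation genes 3 rose and 1 fell with siERRa-D, and 2 fell with siERRa-I (camera adjusted p = 0.595 and 0.651). In the latter the median of 0.07 and the mean of -0.07 differ in sign. Of 76 mitochondrial ribosomal proteins 2 rose and 12 fell with siERRa-D, and 2 fell with siERRa-I (camera adjusted p = 0.219 and 0.839). Of 76 cytosolic ribosomal proteins 2 rose and 1 fell with siERRa-D, and 1 rose and 1 fell with siERRa-I (camera adjusted p = 0.385 and 0.595). Adjusted over the list alone, none of the complex I genes was called, 4 and 1 fell among complexes II to V, 1 rose and 7 fell in the citrate cycle with siERRa-D, 3 rose and 1 fell with siERRa-D and 2 fell with siERRa-I in fatty acid oxidation, 2 and 1 mitochondrial ribosomal genes fell, and 1 cytosolic ribosomal gene rose with siERRa-D. With the replicate block more members passed, while no list gained a call. For siERRa-D and siERRa-I in turn, complex I then had 12 rises and 4 falls, and 10 rises and 3 falls. Complexes II to V had 2 rises and 12 falls, and 2 rises and 13 falls. The citrate cycle had 4 rises and 10 falls, and 1 rise and 6 falls. Fatty acid oxidation had 7 rises and 5 falls, and 5 rises and 5 falls. Mitochondrial ribosomal proteins had 8 rises and 29 falls, and 7 rises and 9 falls. Cytosolic ribosomal proteins had 21 rises and 5 falls, and 6 rises and 12 falls. Mitochondrially encoded messenger RNAs were not analysed here.

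Of the 28 interferon response genes 4 rose and 1 fell with siERRa-D and 1 rose with siERRa-I, and the list did not pass (camera adjusted p = 0.785 and 0.317; 2 rose and 1 fell, and none, adjusted over the list alone). Of 9 luminal epithelial markers tested 1 rose and 2 fell with siERRa-D and none was called with siERRa-I (camera adjusted p = 0.661 and 0.722; the same counts adjusted over the list alone). Of 5 leukocyte markers tested 1 fell with siERRa-D, CD3D at 1.39 ± 0.458 CPM in siC and 0.228 ± 0.14 CPM (edgeR adjusted p = 0.00407), and none was called with siERRa-I (camera adjusted p = 0.785 and 0.445; 1 fell with each adjusted over the list alone). CD3D was chosen after its value was seen, as was PDGFRB. Of 3 fibroblast markers tested 1 fell with siERRa-D, PDGFRB at 0.497 times the control (edgeR adjusted p = 0.0149), and none was called with siERRa-I. With siERRa-D the TGF-beta list had 5 rises and 6 falls, and its median of 0.33 and mean of -0.05 differ in sign (camera adjusted p = 0.342). The matrix list had 10 rises and 13 falls (camera adjusted p = 0.135) and the integrins 6 rises and 3 falls (camera adjusted p = 0.324). NF-kappaB and cytokine genes had 3 rises and 6 falls with siERRa-D, and their median of 0.02 and mean of -0.17 differ in sign (camera adjusted p = 0.634). Glycolysis genes had 2 rises and 7 falls with siERRa-D (camera adjusted p = 0.276) and hypoxia genes 2 rises and 4 falls (camera adjusted p = 0.363). Actin genes had 7 rises and 8 falls with siERRa-D (camera adjusted p = 0.797) and 1 rise and 5 falls with siERRa-I (camera adjusted p = 0.5). Genes of the epithelial to mesenchymal transition had 5 rises and 3 falls with siERRa-D (camera adjusted p = 0.228) and 1 rise and 2 falls with siERRa-I (camera adjusted p = 0.445). Histone genes had 2 rises and 2 falls with siERRa-D (camera adjusted p = 0.564) and 2 rises with siERRa-I (camera adjusted p = 0.101). The list of ERRα and its coactivators had 1 rise and 3 falls with siERRa-D (camera adjusted p = 0.25) and 1 rise and 1 fall with siERRa-I (camera adjusted p = 0.324). Adjusted over the list alone, these counts with siERRa-D were 6 rises and 6 falls for TGF-beta targets, 11 and 14 for matrix genes, 6 and 4 for integrins, 4 and 6 for NF-kappaB genes, 8 and 8 for actin genes and 2 and 1 for histones, and with siERRa-I 1 rise for histones. With the replicate block, 8 NF-kappaB genes rose and 8 fell with siERRa-D, 15 actin genes rose and 17 fell with siERRa-D, and 9 rose and 11 fell with siERRa-I. With siERRa-D the block gave 9 rises and 6 falls for TGF-beta targets, 7 and 5 for integrins, 5 and 10 for glycolysis, 4 and 11 for hypoxia, 8 and 3 for the epithelial to mesenchymal transition, 3 and 6 for histones, 5 and 6 for interferon response genes, 2 and 2 for luminal, 2 and 1 for leukocyte and 1 and 1 for fibroblast markers. With siERRa-I it gave 2 rises and 5 falls for the epithelial to mesenchymal transition, 1 and 8 for interferon response genes, 1 and 3 for ERRα and its coactivators, 1 and 1 for luminal markers, 2 falls for leukocyte markers and 1 for fibroblast markers. CD3D was among the falls with siERRa-I (edgeR adjusted p = 0.0519, and 0.00016 with the block). The other 15 lists tested between the siRNAs did not pass, the lowest adjusted p being that of cytosolic ribosomal proteins (camera adjusted p = 0.093). Some lists that did not pass did so without 1 library. With siERRa-D these were glycolysis without siERRa-D replicate 1 (camera adjusted p = 0.00801) and the matrix list without siC replicate 2 (camera adjusted p = 0.0311), and with siERRa-I the histones without siERRa-I replicate 2 (camera adjusted p = 0.0191). Between the siRNAs these were hypoxia without siERRa-D replicate 3 (camera adjusted p = 0.0422) and the unfolded protein list without siERRa-I replicate 3 (camera adjusted p = 0.0263). In fry, the epithelial to mesenchymal transition (adjusted p = 0.0125) and ERRα with its coactivators (adjusted p = 0.00349) passed with siERRa-D, the latter also with siERRa-I (adjusted p = 0.0237), and hypoxia between the siRNAs (adjusted p = 0.0385). The list of ERRα and its coactivators includes ESRRA, the target of both siRNAs, and its 1 fall with siERRa-I is ESRRA itself. Its fry results therefore say nothing about the coactivators alone.

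**Figure D4:**
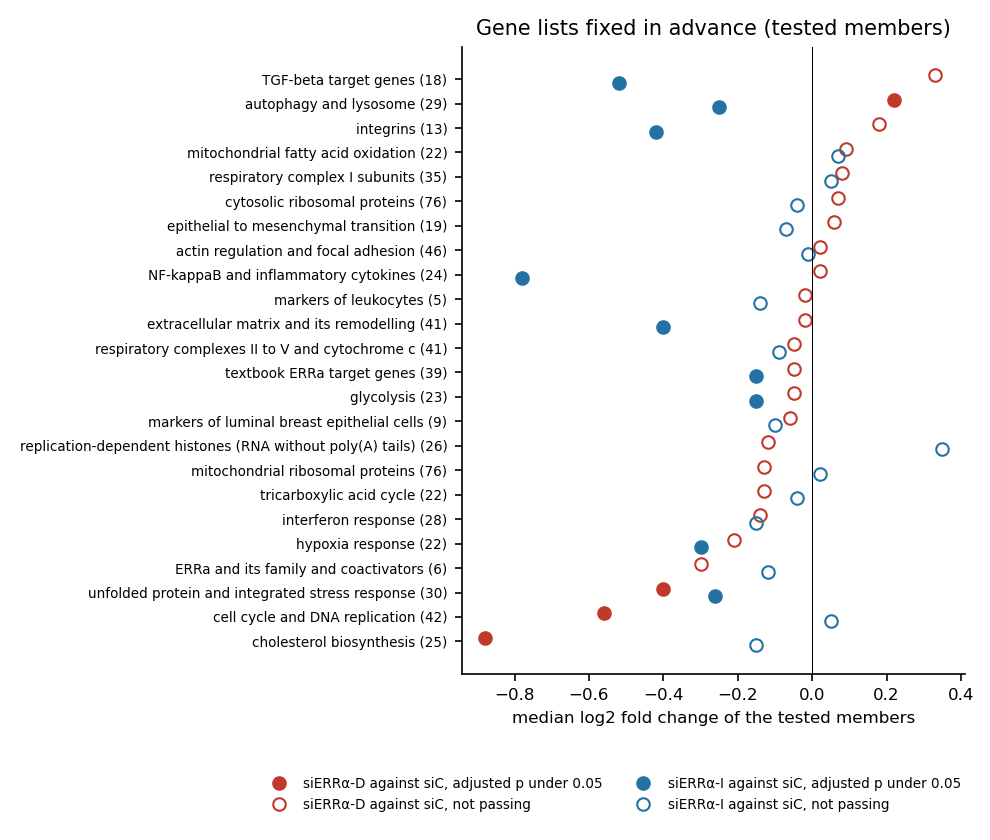
Median log2 fold change against siC of the tested members (number in brackets) of each list with at least 5 tested members, for siERRa-D in red and siERRa-I in blue; filled points passed the camera test with its preset correlation. Cholesterol biosynthesis (-0.88) and the cell cycle (-0.56) stand lowest with siERRa-D, and NF-kappaB and cytokine genes (-0.78) and TGF-beta targets (-0.52) with siERRa-I.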

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

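The tests of a stronger knockdown and of the level of ESRRA with siERRa-D, and the corrections for GC content and length, were chosen after the result was seen. A total of 35 genes passed in both single comparisons with opposite signs, and DUSP10 had the largest difference among them, with siERRa-I below siERRa-D by a log2 difference of -2.05 (edgeR adjusted p = 0.000136). The autophagy and lysosome list passed as higher with siERRa-D and lower with siERRa-I with the preset correlation but not with an estimated one (adjusted p = 0.471 and 0.392), the former also not without siC replicate 2 (0.0532) or siC replicate 3 (0.08). The test of the difference gave a camera adjusted p = 1.36e-09, or adjusted p = 0.0953 with an estimated correlation, which was the highest over all alternatives (lowest 1.52e-10). Uniquely aligned reads outside annotated genes, which no comparison of genes uses, made up 24.2% of reads in siERRa-I against 21.8% in siC. The lowest siERRa-I library lay above the highest siC library (23.5% against 22.6%), with an exact two-sided permutation p of 0.1, the smallest that 3 against 3 libraries can give. Paired by replicate number, the share was above that of siC in 3 of 3 pairs with siERRa-I and also with siERRa-D. No explanation of that share was tested.

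For the 1146 genes changed the same way by both siRNAs, trends with GC content and transcript length were removed from each library. Of the 1095 genes with an annotated transcript, 97.3% kept their call after the GC correction and 97.1% after the length correction, which argues against either trend as the whole cause. The GC correction raised the total to 2022. A GC trend was present. Median transcript GC content was 52.9% in the shared rises, 45.8% in the shared falls and 48.1% in the other genes. Its Spearman correlation with the log2 fold change was 0.18 with siERRa-D, 0.21 with siERRa-I and -0.03 between the siRNAs. A general response to transfection with any active siRNA remains open and was not tested, since no siRNA against another gene was included.

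For the 2375 genes that differ between the siRNAs, a stronger knockdown by siERRa-D would have nearly all of them further from siC with that siRNA. Of these genes 26.8% were further from siC with siERRa-I by their estimates, called against siC or not, slightly past the bound of 25% set for this test. With a call against siC required, 372 genes differed in the direction of their siERRa-I change and 1508 in that of their siERRa-D change. The share is therefore weak evidence. The 35 genes of opposite direction argue against a stronger knockdown as the whole cause. The level of ESRRA itself differed by 0.09 on the log2 scale with a 95% interval from -0.43 to 0.61, so a modestly lower level with either siRNA cannot be told apart from none. Effects of an siRNA on other messages than ESRRA remain open, and the tests of 3' untranslated regions under the other observations bear on them.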

How the results depend on the processing

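The corrections for GC content and length, alone and with the block, were chosen after the data were seen. With the replicate block the counts rose to 7630 genes for siERRa-D against siC, 5852 for siERRa-I against siC, 7189 for their average, 5872 for siERRa-I against siERRa-D and 3639 changed the same way by both, and every gene called without the block was still called. The last count was 2022 after the GC correction, 3640 with block and GC correction and 3552 with block and length correction. The cause was not tested. With an estimated correlation, 0, 0 and 0 lists passed in camera, against 4, 9 and 9 with the preset one. With fry, which does not compare a list with other genes, 8 lists passed for siERRa-D, 9 for siERRa-I and 10 for their difference.

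Leaving out 1 library gave 2760 to 4496 genes for siERRa-D, 797 to 2406 for siERRa-I, 1945 to 3619 for the average, 1192 to 2665 for the difference and 536 to 1232 for both. The single libraries that moved a count by over 1.5 times stand beside the counts in the report. Groups of 2 libraries have less power, these fits had no replicate block, and the cause was not tested further. Counts under DESeq2, RLE size factors, no filter, a minimum mean of 2 CPM and fits of the groups compared stayed within 1.5 times. ESRRA kept its call throughout, at -2.49 to -1.96 with siERRa-D and -2.14 to -1.96 with siERRa-I when 1 library was left out. Of 234 calls of named genes, 52 were lost without some library, 13 without a filter, 4 with only the groups compared in the fit and 0 with DESeq2, RLE factors, the block or the stricter filter. No result changed direction past its threshold. In simulated data of this depth, with 14235 of 14435 genes unchanged, 23 of 100 changes of 0.5 log2 were recovered, so small changes can be missed. That share need not hold in the real comparisons, where far more genes were called.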

Other observations

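The test of the ESRRA motif was chosen after the result was seen, and the list of YAP/TEAD genes was added after the data were seen. Of the 35 genes that moved in opposite directions, most were higher with siERRa-D and lower with siERRa-I. TGFBR2, the type II TGF-beta receptor, had log2 fold changes of 0.86 with siERRa-D and -0.49 with siERRa-I (edgeR adjusted p of the difference = 0.000318). The interleukin-1 receptor genes IL1R1 (0.36 and -0.66) and IL1RAP (0.41 and -0.53) moved likewise, as did FTH1, ferritin heavy chain (0.95 and -0.52), and KYNU, of tryptophan breakdown (0.82 and -0.84). IGFBPL1 (-0.72 and 0.67) and the glycogen phosphorylase gene PYGL (-0.49 and 0.42) went the other way. With the replicate block 357 genes were of opposite direction. These genes were chosen after their values were seen.

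CCN2 is also a target of YAP and TEAD, so 22 other target genes were tested. ANKRD1 fell by 2.33 on the log2 scale with siERRa-D and by 1.09 with siERRa-I, and CCN1 and CCDC80 fell by 1.71 and 1.45 with siERRa-D and were also called lower with siERRa-I, while AMOTL2 and AXL were not called (edgeR). In the list 6 fell and 1 rose with siERRa-D, and 7 fell and 1 rose with siERRa-I, with medians of -0.21 and -0.20 (10 fell and 4 rose, and 10 fell and 3 rose, with the replicate block). The unadjusted camera p was 0.00104 and 0.000264, but with an estimated correlation the larger p was 0.161, so lower expression of the list as a whole was not shown. The 22 calls of the lists fixed in advance did not hold with an estimated correlation either, so by that standard this list does not stand apart from them.

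An siRNA can lower messages whose 3' untranslated region matches its seed. Among 15946 motifs of 7 bases in 12407 genes, that most associated with lower levels under siERRa-D than under siERRa-I was TCTCAGA, and under siERRa-I GTGCATT. Of the genes that fell with siERRa-D and differ, 25.1% carried TCTCAGA against 19.1% of matched genes, an excess of 6 percentage points, and for siERRa-I the excess was 14.7 points. These excesses are too small for direct matches to these motifs to account for most of the falls that differ between the siRNAs. Rises, and effects that follow from a matched gene, were not covered. Both motifs passed in the scan (Bonferroni-adjusted p of the regression t = 5.56e-15 and 7.26e-06). Of genes with the longer site ATCTCAGA 11.9% fell with siERRa-D and differed, against 5.9% of other genes, not matched for length or GC content. Neither TCTCAGA nor GTGCATT occurs in the ESRRA message. The reverse complement of GTGCATT does, but 11.7% of the tested motifs occur in that message, so this match is weak evidence for a link of siERRa-I. The shifted siERRa-D motif TATCTCAG occurs in it, and with the reverse complement of another leading siERRa-D motif it spans 17 bases there. Of random motif pairs shortened to 6 bases 0.46% lay within a window of 21 bases, so a seed is a candidate explanation of part of the siERRa-D effects, from motifs picked after the scan. Cholesterol genes without any of the 5 leading motifs still differed by a median of 0.59, and cell cycle genes by 0.64, which argues against direct matches as the whole cause of these list changes. The siRNA sequences were not given in the sources used here.

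Other splits of the libraries were fitted in the same way. For siERRa-D against siC, siERRa-I against siC and their difference, the real splits gave 4099, 1898 and 2375 genes and the highest other split 0. In each case 1 of 10 splits reached the real count, and 10 splits are too few for a share under 0.05. For the average of both siRNAs 1 of 100 splits, the real one, reached 3448 genes, the highest other giving 2317, and for genes changed by both 1 of 100 reached 1146, the highest other giving 924. These splits ignore the pairing by replicate number, which the data show, so libraries are not freely exchangeable and these shares cannot exclude chance. Those highest others took all 3 siERRa-D libraries as the control set and mixed siC with siERRa-I libraries in the other sets. Their counts thus carry the difference of siERRa-D from siC as well as from siERRa-I. A split with all 3 siC libraries as the control set and the siRNA libraries mixed gave 1869 and 600. Only 10 of the splits, the real one included, part as many replicate pairs, too few for a share under 0.05, and the highest other counts among them were 1901 and 784, and with a control set from mixed groups no split passed 68 and 1.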
